A study of Brassica napus with 12 samples.

How the data were processed

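Polysomal RNA was measured in the fourth leaf of 26-day-old canola plants, grown 2 weeks on agar and 12 days in soil without treatment, per the labels' protocols. Libraries were sequenced at BGI, per the labels' protocols. The submitters' processing notes name GSNAP and SAMtools, without versions or roles. The genome, the annotation, the counting program and whether strand was used are not given in the sources used here. Without that, reads shared between near-identical gene copies, which are common in this polyploid crop, could have been split, dropped or counted at 1 copy, and overlapping genes could share reads. An ID that is high in one experiment and at 0 in the other could in part reflect how reads were assigned between copies.

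The deposited file holds read counts per gene ID, made by the authors and not normalized, with 1 column per library. Totals ran from 36210542 to 42696798 counts per library. Every one of the 12 columns was matched to its sample by name, and 0 columns of other samples were present. All values were even, with 0 odd ones, as if both mates of a read pair had been counted, so a total may count each fragment 2 times. Such doubling changes the weight a count model gives to counting noise, and counts divided by 2 were added as an alternative. The p-values rest on the spread between libraries, and an ID at 0 was given a floor of 3 read pairs, 6 counts, per library, which covers counting error only.

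The IDs carry no gene names, and 0 of them matched the RefSeq gene table supplied for the species. The 23 gene lists fixed beforehand (alternative respiration, respiratory chain, TCA cycle, NAD(P)H supply, drought and abscisic acid response, marker lists of other leaf cells and others) could therefore not be tested. No gene function is given for the same reason.

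Tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr over the 5 groups with a minimum count of 10, and the quasi-likelihood F-test in 1 fit over all 12 libraries with 1 mean per group. P-values were adjusted by Benjamini-Hochberg over the 36410 tested IDs, with a threshold of 0.05. Standard errors of log2 fold changes were taken from the F statistic. Set tests used camera and fry in limma 3.58.1. DESeq2 1.42.0 was an alternative tool. CPM values are counts scaled to the TMM-scaled library size. Principal components used log2 CPM with a prior count of 2. The alternatives were DESeq2's size factors, upper-quartile scaling, DESeq2, no filter, a filter of 5 CPM in at least 2 libraries, libraries of 1 experiment only, the replicate number as a block, a 2-fold minimum, and each library left out in turn. The comparisons, tests, rule for named IDs and these alternatives were set before the data were examined. The blocked fit as a result of its own, the mean effect of the 3 lines, the 65-ID set and the runs were added afterwards.

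Same-numbered libraries were checked for pairing by correlating their deviations from their group means over 17413 IDs. In the EUE experiment the 3 same-numbered pairs had r from 0.60 to 0.73, other pairs at most -0.06, and all 6 libraries correlated best with their own number. Each pair passed the minimum of 0.1, so the numbers were taken to pair the EUE libraries. This comes from the data, since the labels do not say what a number marks. Deviations from a group mean cancel out, so the negative r of other pairs and the 6 best matches are not separate evidence. The 3 numbers can be matched between the groups in too few ways for a share under 0.05. The EUE pairing is therefore an assumption drawn from r and was not tested. The PEG groups have only 2 numbers, so they were taken to share a number only. The blocked fits over all libraries still held a block for the PEG numbers.

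The rule for named IDs took those with an adjusted p under 0.05, a mean of at least 5 CPM over the compared libraries, and every library of one group on the same side of every library of the other. Because the IDs have no names, at most 2 that rose and 2 that fell were named per comparison. Others were named after their values were seen, and the text says so. Names in the EUE comparison and in the mean of the 3 lines come from the blocked fit, a use of the rule chosen after the unblocked fit had no call there. No replicates agreed within sampling noise: on halved counts the chi-square per gene between replicates was 16.9 to 54.9, where sampling noise gives about 1.

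The fits were tested on simulated counts over 35728 genes with 200 changed genes. The changed genes were drawn from those with a mean of at least 5 CPM. The counts were drawn from the blocked fit, with its block effects and its spread. The rates below thus hold for abundant IDs only, and the advantage of the blocked fit was built in. For the EUE epiline, the unblocked fit recovered 4.29% of 2-fold, 81.4% of 4-fold and 96.7% of 8-fold changes with 0 false calls. The blocked fit recovered 85.7%, 100% and 100%, with 17 false calls among 207. For PEG-1 the unblocked fit recovered 0%, 57.1% and 85%, with 0 false calls. In the unchanged PEG-2 both fits called 0.

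For runs of neighbouring IDs, IDs with a mean of at least 2 CPM were put in order of their ERF or ERC number, and the largest running median over 20 IDs of the log2 difference (pseudocount 0.5, single IDs limited to ±3) was set against 1000 shuffled orders. In simulated orders of 4000 IDs, a run shifted by 0.8 was found in place in 10 of 10, and 1 of 10 searches without a run passed 0.05. These steps used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.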

Results

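Canola (Brassica napus) lines that had been selected for low respiration and a high NAD(P)H content were compared with unselected control lines at the level of ribosome-bound mRNA in the leaf. The fourth leaf of 26-day-old plants was collected without any treatment, polysomes were pelleted through sucrose, and their RNA was sequenced. Polysomal RNA is the part of the mRNA that is loaded with ribosomes, so a value here reflects both how much of a transcript there was and how much of it was being translated. Total RNA was not analysed here, so these 2 parts could not be separated.

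The 12 libraries formed 5 groups in 2 experiments. The PEG experiment held a control line, the selected line PEG-1 and the selected line PEG-2, with 2 libraries each. The EUE experiment held its own control line and 1 selected line, called the EUE epiline, with 3 libraries each. The conditions of selection may have differed between the 2 experiments, so they are not taken as repeats of the same selection. The labels call the libraries biological replicates. Total counts ran from 36210542 in PEG-2 replicate 2 to 42696798 in EUE control replicate 3. Of 60756 gene IDs, 13162 had no count in any library and 36410 were abundant enough to test. The IDs carry no gene names, so genes are given by ID only and no pathway could be assigned. An ID is either a single number with the prefix ERF or ERC, or a joined pair of both. Joined IDs held between 70.2% and 71.9% of the counts of each library, and 17297 of them were tested.

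The experiments differed more than the lines within them. The first principal component took 47.4% of the variance and put all 6 PEG libraries at negative scores, from -113 to -25.3, and all 6 EUE libraries at positive scores, from 55.1 to 129. The second component took 13.2%. PEG control replicate 1, at 79.1, and EUE control replicate 2, at 87.6, stood farthest out on its positive side, and EUE epiline replicate 3, at -87.3, on its negative side. Replicates of 1 group therefore lay far apart, and the biological coefficient of variation over all genes was 32.2%. The 100 most abundant IDs took 38.8% ± 0.129 (SD, n = 2) of the counts in the PEG control and 36.1% ± 1.57 (SD, n = 3) in the EUE control. They took 34.6% ± 0.608 (SD, n = 3) in the EUE epiline.

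**Figure D1:**
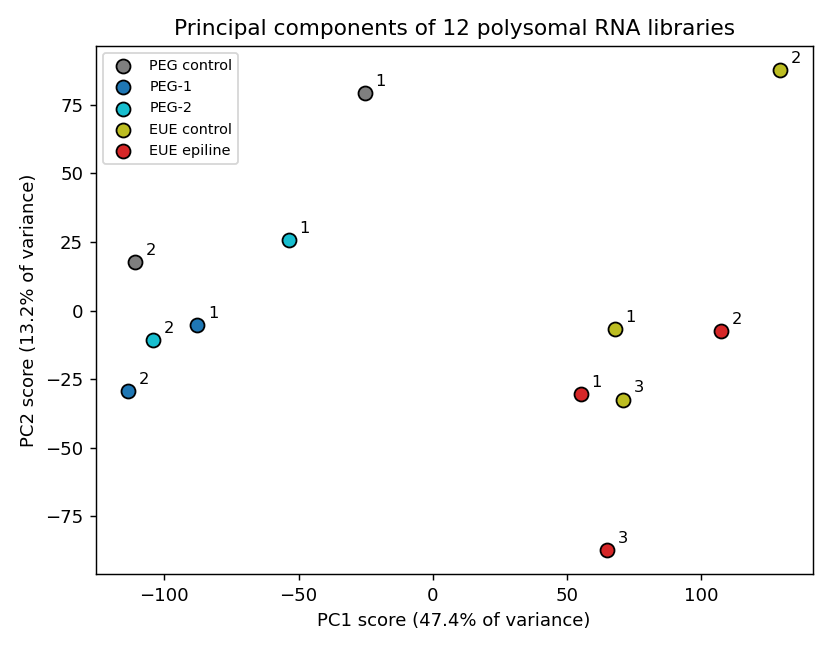
Scores of the 12 libraries on the first 2 principal components of log2 CPM, with each component's share of the variance on its axis; colours mark the groups and the numbers are replicate numbers. The 6 PEG libraries lie left of 0 and the 6 EUE libraries right of it, and PEG control replicate 1 and EUE control replicate 2 lie highest.

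The EUE epiline was compared with the EUE control to ask which ribosome-bound transcripts differ after selection in that experiment. In the design set beforehand, with 1 mean per group, edgeR's quasi-likelihood test called 0 of 36410 IDs. The smallest adjusted p was 0.138, and 1519 IDs had an unadjusted p under 0.05, where 1820.5 would by chance. Of the 1519, 1288 were higher and 231 lower in the EUE epiline. DESeq2 on the same libraries called 382 IDs, 372 of them higher. Same-numbered EUE libraries deviated together, and with the replicate number as a block edgeR called 69 IDs, of which 65 rose and 4 fell. The EUE pairing was taken from these same data. That fit took the PEG numbers as blocks too, though their pairing is not established. Its biological coefficient of variation was 18.7%, against 32.2% without the block. The 65 had a median log2 fold change of 2.88 without the block, 7.36-fold.

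Among the 33 IDs that met the rule for named IDs in the blocked fit, all of which rose, ERF79322-ERC45551 had the largest change. Its level was 10.7 ± 7.86 CPM (SD, n = 3) in the EUE epiline and 0.439 ± 0.278 CPM (SD, n = 3) in the control. Its log2 fold change was 4.28 with a standard error of 0.672 in the blocked fit (edgeR adjusted p = 0.0476; 0.272 without the block). ERF81066-ERC23699 followed, at 14.1 ± 9.98 CPM (SD, n = 3) against 0.624 ± 0.186 CPM (SD, n = 3), with a log2 fold change of 4.17 and a standard error of 0.554 (edgeR adjusted p = 0.0468 with the block, 0.272 without). In both, EUE epiline replicate 1 was the lowest of the selected line, at 1.74 and 2.98 CPM, and still above all 3 control libraries. The adjusted p of these IDs ranged from 0.000301 to 0.434 and from 5.04e-06 to 0.394 over the alternatives, and both calls ended without either PEG-1 library, either PEG-2 library, EUE control replicate 2 or 3, or EUE epiline replicate 2 or 3. They also ended in the blocked fit on the EUE libraries alone, with adjusted p of 0.205 and 0.202 in edgeR, where the log2 fold changes were 4.32 and 4.19. ERF86571-ERC26059, named after its values were seen because it had the smallest p in the unblocked fit, was at 0.0465 ± 0.0450 CPM (SD, n = 3) in the EUE epiline and 2.15 ± 0.225 CPM (SD, n = 3) in the control. Its counts were 0 to 4 in the selected line and 82 to 92 in the control, and its edgeR adjusted p was 0.138 without the block and 0.0412 with it. Over its alternatives the adjusted p ranged from 7.33e-10 in DESeq2 to 0.583 without EUE control replicate 3.

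The count of 69 was 2 when only the EUE libraries entered the blocked fit, 217 with counts divided by 2 and 766 in DESeq2 with the block. It also depended on single libraries, those of the PEG experiment included. It rose to 1032 without EUE control replicate 1 and to 1030 without EUE epiline replicate 1. It fell to 1 without EUE control replicate 2, either PEG-1 library or either PEG-2 library. It fell to 0 without EUE control replicate 3, EUE epiline replicate 2 or EUE epiline replicate 3. In the unblocked fit, leaving out EUE epiline replicate 1 raised the count from 0 to 205.

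**Figure D2:**
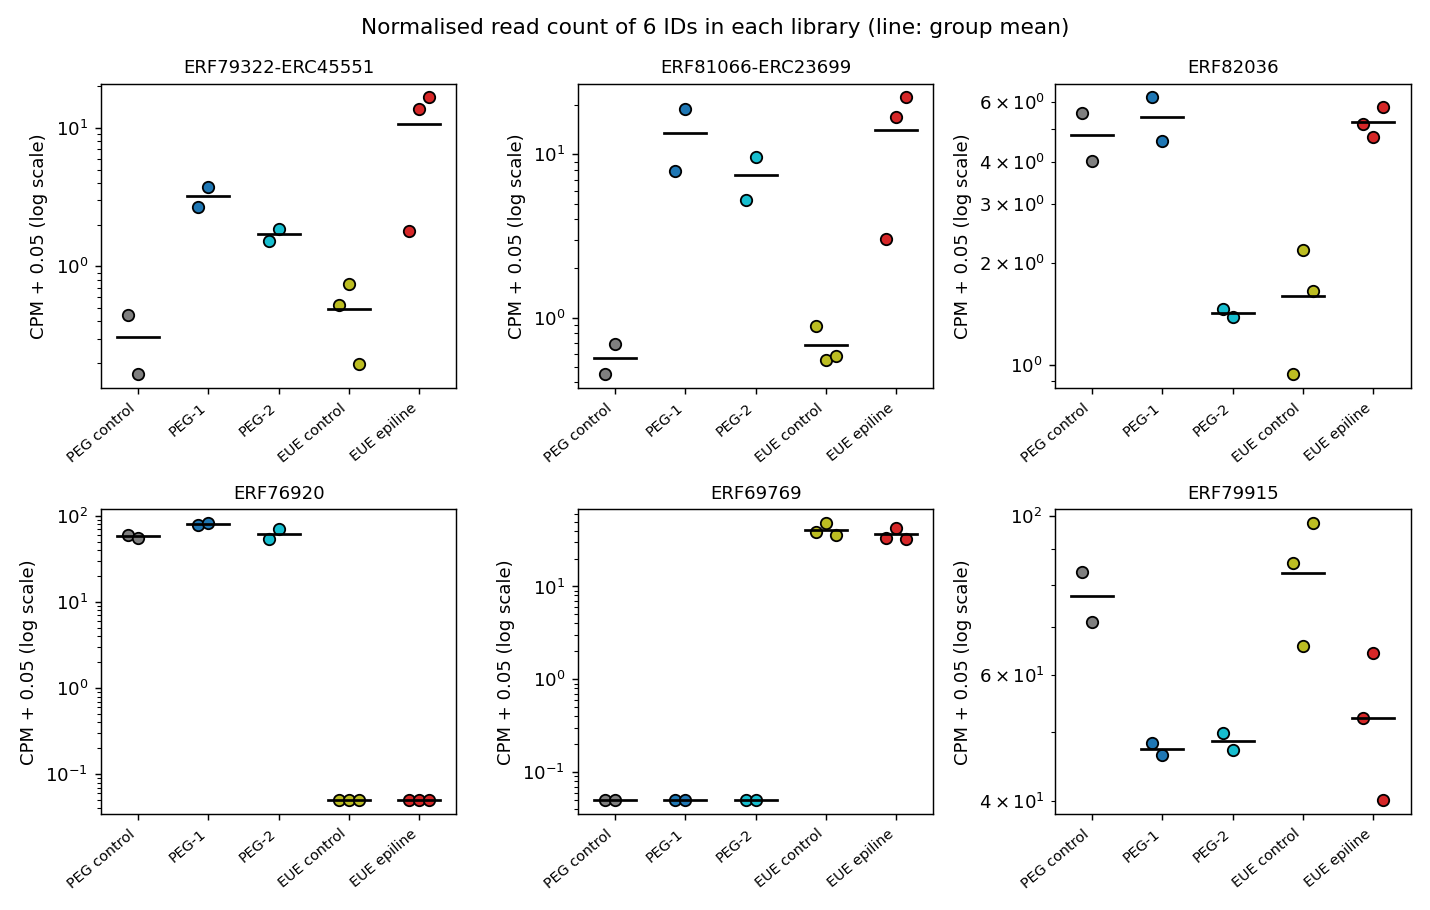
Normalised read count of 6 IDs in each library, in CPM plus 0.05 on a log axis; points are libraries, coloured by group, and lines are group means. ERF79322-ERC45551 and ERF81066-ERC23699 are higher in all 3 selected lines than in either control, ERF82036 is low in PEG-2 and in the EUE control, ERF76920 and ERF69769 have 0 counts in every library of one experiment, and ERF79915 is lower in all 3 selected lines.

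PEG-1 was compared with the PEG control to ask what changed in the first line of that experiment. In the design set beforehand edgeR called 0 of 36410 IDs, with a smallest adjusted p of 0.749, and 1310 IDs had an unadjusted p under 0.05, 684 of them higher and 626 lower. By chance 1820.5 IDs would have such a p. DESeq2 called 145 IDs on the same libraries, 132 of them higher. ERF70161-ERC56186 had the smallest p and was named after its values were seen. It was at 7.04 ± 1.59 CPM (SD, n = 2) in PEG-1 and 1.86 ± 0.347 CPM (SD, n = 2) in the control, a log2 difference of 1.92 with a standard error of 0.346 (edgeR adjusted p = 0.749; 0.000369 to 1 over the alternatives, the lowest in DESeq2). It was at 5.76 ± 0.405 CPM (SD, n = 2) in PEG-2. On simulated data with groups of this size, the test recovered 0% of 2-fold, 57.1% of 4-fold and 85% of 8-fold changes in PEG-1 among 35728 genes. All changed genes there had a mean of at least 5 CPM, so rates for scarcer IDs are not known.

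PEG-2 was compared with the same PEG control libraries. Again edgeR called 0 of 36410 IDs, the smallest adjusted p was 1, and 684 IDs had an unadjusted p under 0.05, 375 of them higher and 309 lower. Here too 1820.5 would by chance. DESeq2 called 17 IDs, 15 of them higher. ERF55132-ERC31643, named after its values were seen for its smallest p, had no count in either PEG-2 library and 0.715 ± 0.196 CPM (SD, n = 2) in the control, 20 and 30 counts. With a floor of 3 read pairs per library it was at least 3.16-fold lower in PEG-2, and its edgeR adjusted p was 1 (0.0362 in DESeq2, the lowest of the alternatives). Between PEG-2 and PEG-1, edgeR called 0 IDs with 591 at an unadjusted p under 0.05, where 1820.5 would by chance. DESeq2 called 1 ID there.

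The IDs that rose in the EUE epiline with the block were then followed in the PEG lines. PEG libraries entered their selection only through the abundance filter, the scaling and the shared estimate of the spread, taken with the PEG numbers as blocks. In PEG-1, 63 of the 65 had a positive log2 fold change, the median was 2.57, or 5.95-fold (2.47 with a prior count of 2), and both PEG-1 libraries lay above both controls for 56 of them. Among all tested IDs 14.7% did so, and chance gives 16.7% for a single ID. In PEG-2, 62 of the 65 were positive, the median was 1.79, or 3.45-fold (1.77 with the prior count), and both libraries lay above both controls for 50 of them, against 13.1% of all tested IDs. The 65 IDs moved together, with a correlation of 0.52 estimated by camera in either PEG line, so 56 and 50 do not count separate trials. A set that moves as 1 block would lie above both controls together with that same chance of 16.7%. The same 65 IDs also differed between replicates of 1 group. Replicate 2 lay above replicate 1 by a median log2 difference of 1.19 in PEG-1, 1.11 in PEG-2 and 0.46 in the PEG control. ERF81066-ERC23699 showed this in single libraries. It was at 13.4 ± 7.85 CPM (SD, n = 2) in PEG-1, 7.41 ± 3.11 CPM (SD, n = 2) in PEG-2 and 0.516 ± 0.167 CPM (SD, n = 2) in the PEG control.

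As a set, the 65 IDs stood above the other IDs in PEG-1 by camera with an estimated correlation of 0.52 (adjusted p = 0.0404 over 4 set tests). In PEG-2 camera with an estimated correlation, also 0.52, gave an adjusted p of 0.0548, so the set did not pass. With a preset correlation of 0.01 camera gave adjusted p of 1.57e-56 in PEG-1 and 7.22e-37 in PEG-2. The preset lies far below the estimate, so these 2 values overstate the evidence. Without the block, the fry test in limma of whether the set moved one way gave an adjusted p of 0.0876 in PEG-1 and 0.198 in PEG-2. The values with the block, under which the set was chosen, are given with the alternatives. Leaving out any 1 PEG library kept the median log2 difference between 1.86 and 2.99 in PEG-1 and between 1.15 and 2.36 in PEG-2. The 4 IDs that fell in the EUE epiline had medians of -0.06 in PEG-1 and -0.12 in PEG-2.

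The fold changes were also compared over all genes. Across 17413 IDs with a mean of at least 5 CPM, the fold changes of PEG-1 and the EUE epiline correlated with r = 0.70. These comparisons share no library, though genes are not independent replicates. An exact test over the 30 joint splits of their libraries gave p = 0.0333, adjusted 0.0667 over the 2 relations tested. For PEG-2 and the EUE epiline r was 0.63 (exact p = 0.0667, adjusted 0.0667). These splits mix replicate numbers. Only 12 of them part every EUE pair, and among those both values were the highest, at the smallest exact p they allow, 0.0833. With the PEG numbers kept too, 8 splits remain and the smallest exact p is 0.125. With the replicate axes removed, r was 0.54 for PEG-1 and 0.52 for PEG-2. The value for PEG-1 fell to 0.42 without EUE control replicate 2, and the value for PEG-2 fell to 0.29 without PEG control replicate 1 and to 0.40 without PEG-2 replicate 2.

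**Figure D3:**
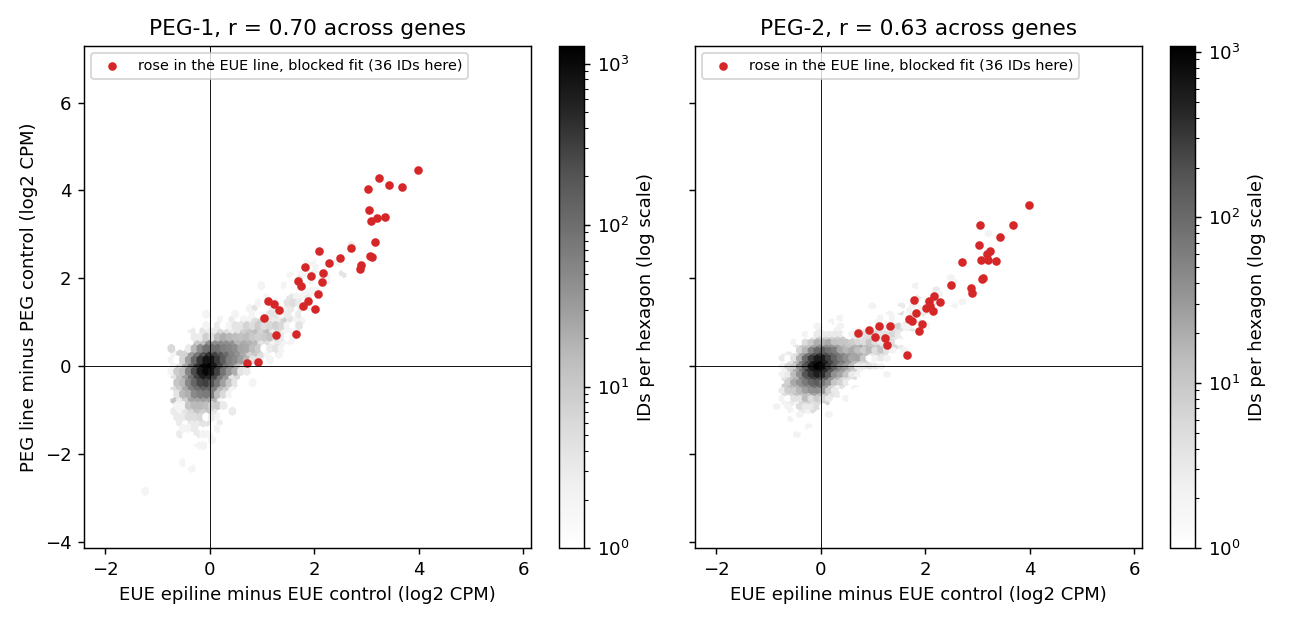
Log2 differences of the EUE epiline from its control (horizontal axis) against those of PEG-1 (left) and PEG-2 (right) from the PEG control, for 17413 IDs with at least 5 CPM; grey hexagons show the number of IDs on a log scale and red points the IDs that rose in the EUE epiline in the blocked fit. The cloud runs from the centre to the upper right in both panels, with r = 0.70 and r = 0.63.

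Of the 200 IDs with the smallest p among those with a positive log2 fold change in each comparison, 117 were common to PEG-1 and the EUE epiline and 88 to PEG-2 and the EUE epiline, where independent lists would share 1.1. Of the 200 with a negative one, 5 were common in either pair. The value of 1.1 takes IDs as independent, and IDs that move together can make lists overlap by far more. Other joint splits of the libraries reached absolute correlations of up to 0.65 for either PEG line with the EUE experiment. Overlaps under such splits were not computed, so the size of the excess is not known. PEG-1 and PEG-2 shared 118 positive and 18 negative IDs, but they also share their control libraries. In 20 simulations of unchanged PEG groups the mean overlap was 42.5 positive and 16.5 negative IDs. Every library and ID was drawn separately there, without the IDs that move together or the shared replicate differences of the real libraries. Real unchanged groups could thus overlap and correlate more than the simulated ones, so an excess over them does not show a shared effect. The correlation of PEG-1 and PEG-2 was 0.72 against 0.50 in those simulations. The covariance was 0.0854 against 0.0788, a difference of 0.00665, and part of any excess may come from the shared controls, which could not be split. In edgeR's fit over all libraries without the block there were 0 calls to share. DESeq2's calls shared 112 IDs between PEG-1 and the EUE epiline, where independent lists would share 1.35. That value too takes IDs as independent. Between PEG-1 and PEG-2 DESeq2's calls shared 15 IDs, for which the shared controls leave no such value.

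Whether a PEG line and the EUE epiline differ in their effects was tested directly. For PEG-1 edgeR called 0 IDs, with 405 at an unadjusted p under 0.05, and DESeq2 called 1. For PEG-2 edgeR called 0, with 337 at an unadjusted p under 0.05, and DESeq2 called 2. By chance 1820.5 IDs would have such a p in edgeR, so neither count points to a difference. Recovery was not simulated for these 2 tests, so 0 calls do not show that the effects are alike. With each line set against its own control, 752 IDs were higher in every library of PEG-1 and of the EUE epiline than in every library of that control, and 222 were lower in both. In 165 the directions were opposite. For PEG-2 and the EUE epiline 582 were higher in both, 180 lower in both and 153 opposite. From the share of IDs in each direction in each line, taken as independent, PEG-1 and the EUE epiline would have 204 higher in both, 158 lower in both and 365 opposite. PEG-2 and the EUE epiline would have 181, 134 and 315. Where IDs move together, counts can lie farther from these values by chance than for independent IDs.

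The 2 control lines were compared as background, because line and experiment cannot be told apart here. Some IDs were present in one experiment and absent from the other. The PEG control differed from the EUE control in 1072 IDs in edgeR's test, 659 higher and 413 lower, and 402 met the rule for named IDs. ERF76920 was at 58.0 ± 3.02 CPM (SD, n = 2) in the PEG control with 0 counts in all 6 EUE libraries, so it was at least 356-fold higher with a floor of 3 read pairs per library (edgeR adjusted p = 1.31e-05). ERC59102 was at 26.7 ± 1.33 CPM (SD, n = 2) and again 0 in the EUE libraries, at least 164-fold higher. In the other direction, ERF69769 was at 40.6 ± 6.46 CPM (SD, n = 3) in the EUE control and 0 in all 6 PEG libraries, at least 206-fold lower in the PEG control. ERF94153 was at 17.7 ± 1.54 CPM (SD, n = 3) in the EUE control and likewise 0 in the PEG libraries, at least 95.6-fold lower.

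Joined IDs were scarce among the IDs that differed between the controls. They made up 27.6% of the 1072 and 47.5% of all tested IDs, an odds ratio of 0.41 (Fisher's exact test, 2-sided, p = 1.63e-41, genes taken as independent). The count of 1072 fell to 300 without PEG control replicate 2, to 662 without EUE control replicate 1 and to 701 without EUE control replicate 3.

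IDs of 1 class with neighbouring numbers differed together between the control lines, but the classes did not move alike. Put in order of their ERC number, the 20 single IDs from ERC35951 to ERC36108, chosen after their values were seen, were higher in the PEG control by a median of 1.24 on the log2 scale, 2.36-fold, and 16 of the 20 were higher. No shuffled order reached more than 0.719 (permutation p = 0.001, the smallest that 1000 shuffles can give, adjusted 0.005 over 20 searches). The 20 joined IDs with ERC numbers from 35928 to 35976 were lower, with a median of -0.79, in 18 of the 20 (permutation p = 0.001, adjusted 0.005). Of all 60 joined IDs from 35951 to 36108, 39 were lower and 21 higher, with a median of -0.27. PEG-1 against the EUE epiline, which share no library with the controls, gave 1.12 and -0.78 for the 2 runs. Runs passed an adjusted p of 0.05 in all 4 searches between the controls, in 3 of 4 for PEG-1, 2 of 4 for PEG-2, 2 of 4 between PEG-2 and PEG-1 and 0 of 4 for the EUE epiline, so 11 of 20 searches passed. These passes are not all separate runs. Joined IDs were searched in both orders, and overlapping joined runs passed in each, with the same median of -0.34 for PEG-1 and -0.79 between the controls. The single IDs from ERC29129 to ERC29322 passed in both comparisons of PEG-2, as did overlapping runs of single ERF IDs. The largest run within the PEG experiment had a median of -0.43, in PEG-2.

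**Figure D4:**
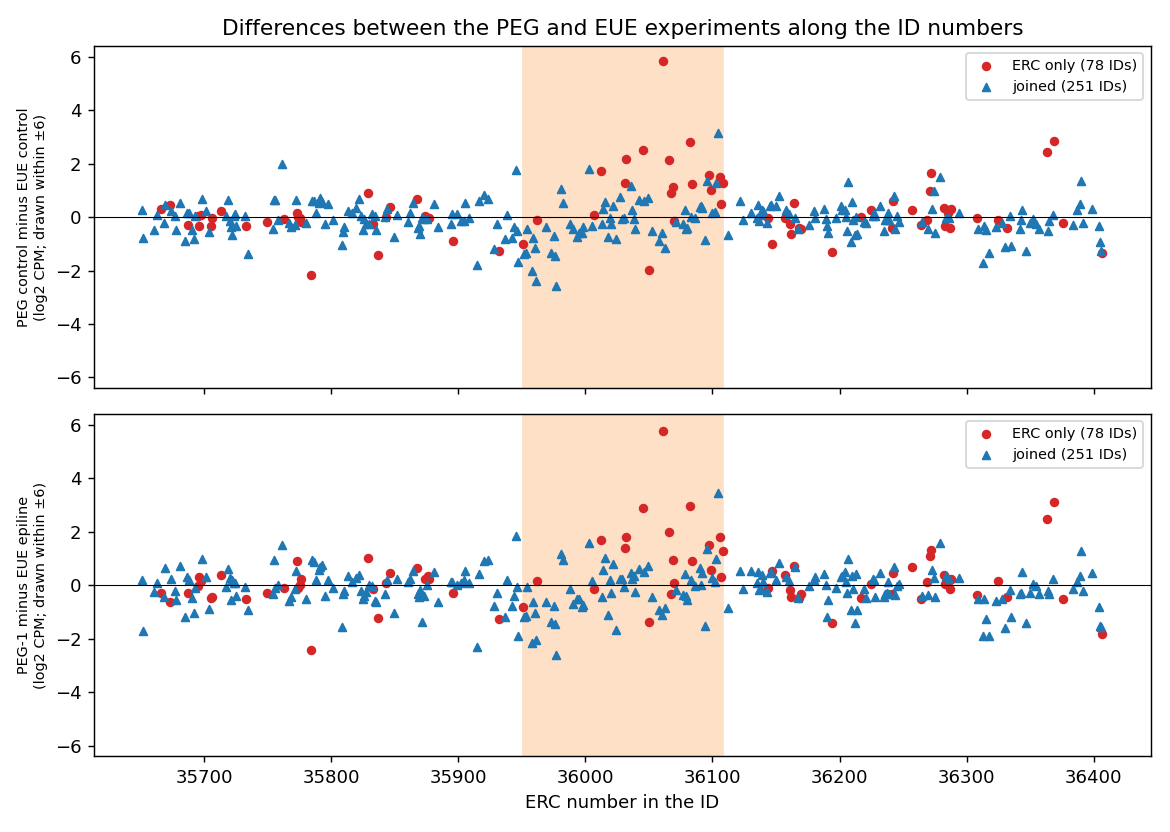
Log2 differences in CPM of the PEG control from the EUE control (top) and of PEG-1 from the EUE epiline (bottom) for IDs ordered by ERC number; points are single IDs, ERC-only or joined, drawn within ±6, and the shaded stretch spans ERC35951 to ERC36108. In the shaded stretch most ERC-only IDs lie above 0 and most joined IDs below 0 in both panels.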

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

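The test of ERF82036 was chosen after its values were seen. Every PEG-2 library was lower than both PEG controls, while every EUE epiline library was higher than all 3 EUE controls. It was at 1.38 ± 0.0576 CPM (SD, n = 2) in PEG-2 against 4.75 ± 1.09 CPM (SD, n = 2) in the PEG control, and at 5.18 ± 0.552 CPM (SD, n = 3) in the EUE epiline against 1.55 ± 0.631 CPM (SD, n = 3) in the EUE control. PEG-1, at 5.35 ± 1.11 CPM (SD, n = 2), lay near its control. The difference of the PEG-2 and EUE effects was -3.52 on the log2 scale with a standard error of 0.494. Its edgeR p was 1.55e-05 and its adjusted p 0.564, so it did not pass over 36410 IDs. Over the alternatives the adjusted p ranged from 5.62e-07 in DESeq2 to 1, as with the stricter filter. No group had 4 or more libraries, so single libraries far from their group were not tested for.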

How the results depend on the processing

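The division of counts by 2, the blocked fits restricted to 1 experiment, and all alternatives to the blocked EUE count and to the mean effect of the 3 lines were chosen after the data were seen. Counts of 0 became 145 (PEG-1), 17 (PEG-2), 382 (EUE epiline), 1 (PEG-2 against PEG-1), and 1 and 2 (differences of PEG-1 and PEG-2 from the EUE effect, ERF82036 among the latter) in DESeq2, which called 2428 IDs between the controls against 1072 in edgeR. DESeq2 overlaps were 15 (PEG-1 with PEG-2) and 112 (PEG with EUE). Without a filter the EUE epiline had 27 calls, and the stricter filter, which tested 20016 IDs, left 506 between the controls. With libraries of 1 experiment only, PEG-1 and PEG-2 each had 1 call, shared by both. Beyond the stricter filter's smaller number of IDs, the cause was not tested.

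With the replicate block the counts were 1 (PEG-1, ERF91342, named after its values were seen), 0 (PEG-2), 69 (EUE epiline), 0 (PEG-2 against PEG-1), 5709 (controls, as the mean over the numbers of each experiment) and 0 for both differences, and 1 ID was shared by PEG and EUE calls. The 2 experiments share no number, so for the controls the block takes spread between replicates out of the error without pairing anything, and the 5709 overstates the evidence beside the 1072. In the PEG experiment same-numbered libraries correlated at 0.53 to 0.69, but with 2 numbers this does not establish pairs. The replicate block with libraries of 1 experiment gave 686 (PEG-1), 208 (PEG-2), 2 (EUE epiline) and 7 (PEG-2 against PEG-1), with overlaps of 184 and 2. With the block the fry adjusted p of the 65 rising IDs was 0.0146 in PEG-1 and 0.0264 in PEG-2, against 0.0876 and 0.198. The blocked EUE count of 69 became 0 without the block, 766 in DESeq2 and 217 with counts divided by 2, and all 69 were among the calls of the last 2. The mean effect's 595 became 1267 in DESeq2, 591 of them shared. Without the block it became 0 in edgeR, and also with either other scaling, the stricter filter, counts divided by 2 or the 2-fold minimum, but 286 with no filter and 584 in DESeq2. Without the block and 1 library it was 120 without PEG-1 replicate 1, 346 without EUE epiline replicate 1 and 0 otherwise. The cause of these shifts was not tested.

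Leaving out 1 library gave 0 to 205 calls for the EUE epiline, 300 to 1067 between the controls, 0 to 1032 for the blocked EUE count and 107 to 1370 for the mean effect. PEG-1, PEG-2, PEG-2 against PEG-1 and both differences stayed at 0 to 0. The correlations ranged from 0.42 to 0.73 (PEG-1 and EUE) and from 0.29 to 0.67 (PEG-2 and EUE). A lone library was assumed to vary like the other groups. RLE and upper-quartile scaling and the 2-fold minimum left every count of calls in the 5 comparisons and both differences within 1.5 times. For the named IDs, 205 of their alternatives left the call as it was, 49 ended it and 8 made one, and 0 turned the direction. Not run: the tests of gene lists, since no ID has a name. Depth limits IDs near the floor of 6 counts per library.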

Other observations

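The tests of the correlations, of the mean effect against other assignments, of the rising IDs between replicates, of the most abundant IDs, of neighbouring IDs and of present and absent IDs were chosen only after the results were seen, as was the mean effect of the 3 lines. The mean effect took the mean of PEG-1 and PEG-2 against the PEG control and averaged it with the EUE epiline against the EUE control. The EUE epiline thus weighed as much as both PEG lines together. With the replicate block, 595 IDs passed in edgeR, 514 higher and 81 lower in this mean. ERF86571-ERC26059 passed almost through the EUE epiline alone (edgeR adjusted p = 0.014). Its log2 fold changes with the block were -0.14 in PEG-1, -0.03 in PEG-2 and -5.45 in the EUE epiline. The medians of the 514 were 3.31-fold in PEG-1, 2.24-fold in PEG-2 and 3.36-fold in the EUE epiline, which follow in part from their selection on the mean of the lines. The block takes the PEG numbers as pairs too, which is not established. Without the block 0 passed in edgeR, with 2086 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0532, but 286 passed with no filter on low counts and 584 in DESeq2, 265 and 418 of them among the 595. DESeq2 with the block called 1267. The count was 107 without PEG-2 replicate 1, 127 and 159 without PEG control replicates 1 and 2, and 1370 without EUE control replicate 1. It was 136 without PEG-2 replicate 2, 173 and 169 without EUE control replicates 2 and 3, 1366, 156 and 153 without EUE epiline replicates 1, 2 and 3, and 374 and 355 without PEG-1 replicates 1 and 2.

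ERF56853-ERC48126 had the largest rise of the 150 IDs that met the rule for this contrast. It was at 11.9 ± 0.630 CPM (SD, n = 2) in PEG-1, 4.58 ± 0.312 CPM (SD, n = 2) in PEG-2 and 24 ± 25 CPM (SD, n = 3) in the EUE epiline. The PEG control was at 0.0573 CPM, 2 counts in each library, and the EUE control at 0.503 ± 0.744 CPM (SD, n = 3); edgeR's adjusted p was 0.0150. The call ended without either PEG control library, either PEG-2 library or EUE epiline replicate 2 (adjusted p up to 0.0945). ERF81066-ERC23699 came second (standard error of the log2 fold change 0.428, edgeR adjusted p = 0.00612), and no left-out library ended its call. Falling IDs changed less. ERF79915 was at 47.3 ± 1.28 CPM (SD, n = 2) in PEG-1 and 48.4 ± 1.92 CPM (SD, n = 2) in PEG-2, against 77.1 ± 8.75 CPM (SD, n = 2) in their control. It was at 52.2 ± 12.2 CPM (SD, n = 3) in the EUE epiline, against 83.1 ± 16 CPM (SD, n = 3) (log2 fold change -0.68, standard error 0.140, edgeR adjusted p = 0.0439). ERF62234 had a log2 fold change of -0.53 (standard error 0.0960, edgeR adjusted p = 0.0278). Without PEG control replicate 1 their adjusted p was 0.220 and 0.167. Either call also ended without PEG control replicate 2, any PEG-1 or PEG-2 library, EUE control replicate 3 or EUE epiline replicate 3, ERF79915's also without EUE control replicate 1 or EUE epiline replicate 1, and ERF62234's without EUE control replicate 2 or EUE epiline replicate 2. Joined IDs made up 56.1% of the 595 and 47.5% of the tested IDs, an odds ratio of 1.42 (Fisher's exact test, p = 2.34e-05, genes taken as independent). They also held 70.2% to 71.9% of the counts of each library, and abundance was not matched in this test.

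Other assignments of the libraries to groups were fitted to see how often they gave as much. For the EUE libraries the 10 splits into 3 and 3 are too few for a share under 0.05. Without the block all 10 gave 0 calls, the highest other being 0, and with it the real split gave 69 and the highest other 3. The other 3 splits that part all 3 pairs gave 0. At an unadjusted edgeR p under 0.05 the real split had 1519 IDs without the block, and other splits had 258 to 5860. With the block it had 3089, and others had 593 to 3111. Other splits that part all 3 pairs had at most 1147 without the block and 2274 with it. For the mean effect, assignments that keep the EUE pairs and move the PEG libraries freely number 360, of which 100 were fitted with the block, and 1 of the 100, the real one, gave as many as 595. The highest other, 497, took PEG-1 as control and swapped every EUE pair, which nearly mirrors the real grouping. The next, 182, kept both real controls and only mixed PEG-1 with PEG-2. Many drawn assignments put same-numbered PEG libraries in 1 group, where the block takes up part of the group difference, so they are not like the real one. Such an assignment had 4746 IDs at an unadjusted edgeR p under 0.05 and 0 calls, against 4588 in the real one. Chance is therefore not excluded for the blocked count. The contrast was also chosen after the results were seen, and without the block the count ran from 0 to 584 with tool and filter. For the correlations the 12 joint splits that part every EUE pair are too few for a share under 0.05. The real values were 0.70 for PEG-1 (highest other 0.619) and 0.63 for PEG-2 (highest other 0.631).

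The rise of the same IDs in all 3 lines may have more than 1 source. If a few abundant genes took fewer of the counts in a line, all other genes would gain alike. The unscaled share outside the 100 most abundant IDs changed by at most 0.033 (log2, EUE epiline). The medians of the 65 rising IDs were 1.79 to 2.88. The share was already 61.2% in the PEG control and 63.9% in the EUE control, so no rise of it could have reached those medians. The outcome of this comparison was thus fixed beforehand, and it is not counted as evidence. A plant state that also varies between replicates stays open. Between the PEG control libraries, replicate 2 exceeded replicate 1 in these 65 IDs by a median of 0.46, at percentile 100 of 10000 random lists matched on abundance, and the PEG-1 and PEG-2 replicates differed by 1.19 and 1.11 the same way. The 65 IDs move together, with a correlation of 0.52 estimated by camera in PEG-1, and random lists do not. A set that moves together can reach an extreme percentile between any 2 libraries, so the percentile does not decide. The 65 IDs did vary within groups too. A difference in plant state between the lines at harvest is thus a candidate explanation, beside selection itself, which the design names and which was not tested apart from it.

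ID numbers appear to follow an order: of consecutive joined IDs sorted by ERF number, 88.6% had ERC numbers within 20 of each other, against at most 0.165% in shuffled orders. Along that order, the run of single IDs from ERC35951 to ERC36108, with a median of 1.24 against a shuffled maximum of 0.719, was the largest between the control lines. A library or sequencing batch between the experiments cannot be told apart from other sources of this run. Runs also passed within the PEG experiment, where such a batch does not act, so IDs of 1 class with neighbouring numbers can move together without it, and the run of 1.24 may be such a joint change. It does not cover the whole stretch, where 39 of the 60 joined IDs were below 0. Different plant stocks behind the experiments stay open too. After IDs at 0 in 1 experiment had been seen, 63 IDs were counted at 1 CPM or more in all 6 libraries of one experiment and at 0.1 CPM or less in all 6 of the other, 42 on in PEG and 21 on in EUE, while 0 IDs did so in any of the other splits among 462. Growth conditions, or reads assigned differently between gene copies, could give the same, so this count does not speak for stocks over them.

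Within the PEG experiment, the 20 single IDs from ERC29129 to ERC29322, chosen after their values were seen, were lower in PEG-2 than in its control by 0.43 (1.35-fold; shuffled maximum 0.364; permutation p = 0.001, adjusted 0.005). They were lower than in PEG-1 by 0.34 (adjusted 0.008). Their median relative to the mean of all libraries was -0.17 and -0.48 in the PEG-2 libraries and between -0.035 and 0.095 in the other 10.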
